A study of Drosophila melanogaster with 8 samples.

How the data were processed

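The series holds 8 single-colour arrays of RNA from Drosophila central brain taken at 24 h after puparium formation (APF) from flies raised at 29 °C, with the label female. The 4 control samples carried elav-Gal4, which drives Gal4 in neurons, and UAS-dicer2, which raises the level of the RNA interference enzyme Dicer-2. The 4 knockdown samples carried in addition a UAS hairpin against DIP2. Groups and replicate numbers were taken from the sample titles, and the submitters call the replicates biological.

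Per the labels' protocols, total RNA was purified on RNeasy columns, checked by NanoDrop and Experion, and amplified and labelled with Cy3 by Agilent's Low-Input QuickAmp kit. Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1 in its single-colour gene expression protocol, with probe positions on genome build dm3. The deposited scanner files give an intensity for each spot on a linear scale. Per the file headers, this processed intensity was background-subtracted within each array with spatial and multiplicative detrending, low values were replaced by surrogates, and nothing was scaled between arrays. The deposited files also give the unsubtracted spot and background intensity, together with flags for spots well above background, saturated spots and outlier spots. The authors' value table of the series holds log2 values for the same spots. The medians of its 8 columns lay between 7.12 and 7.13, and over spots each column correlated with the log2 of that array's unsubtracted spot intensity at an r of 0.996 or more and with the log2 of its processed intensity at 0.961 to 0.981. Its scale is therefore log2 and it has no centring by gene, but the exact normalization is not given in the sources used here.

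Each array held 43602 spots besides control spots, for 32162 different probes. The 75th percentile of the processed intensity ran from 443.7 (control 3) to 896.5 (DIP2 knockdown 3), and the share of spots well above background from 52.3% (control 4) to 73.6% (DIP2 knockdown 2). No spot was saturated, and 75 to 522 spots per array carried an outlier flag, the most on control 4. The precision of each value is limited by the number of arrays, 4 per group. Rank correlations between any 2 arrays over genes lay between 0.976 and 0.991, so no array repeated another. The arrays were on 2 slides of 4, with replicates 1 and 2 of both groups on slide 1 and replicates 3 and 4 of both on slide 2, and each slide was scanned as a unit. On both slides the control samples took positions 1 and 3 and the knockdown samples positions 2 and 4, so position and group cannot be told apart.

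For the comparison, the log2 of the processed intensity was taken minus each array's 75th percentile. Control spots and spots flagged as non-uniform or population outliers were left out, and the spots of a probe were averaged. A probe entered if it was well above background on all arrays of at least 1 group, where a probe counted as such on an array if this held for a share of at least 0.5 of its spots. A gene was represented by its brightest probe over all 8 arrays. For genes that changed and are named, probes that disagree are named with the gene. For list members given only as values, the value is that of the brightest probe, and other probes can differ in size and sign. Examples are shot (0.26, and -0.36 at its lowest probe), Mical (0.16 and -0.51) and Mef2 (0.21 and -0.65). Probes were named through the reference gene table of the Release 6 assembly, by annotation number, RefSeq accession, symbol or synonym. Of the 32162 probes, 21074 were named this way (13133 genes), and 11088 kept the identifier of the file and are called transcripts without a gene symbol. The reference served for names only, and positions are those of the files on dm3. Which exon or untranslated region a probe lies in is not given in the sources used here.

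Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are knockdown minus control and errors beside them are standard errors of that fit. Where a probe was well above background on no array of a group, the fold is given against a floor. It compares the mean of the brighter group with a mean over the dimmer group's arrays. On each of these arrays the higher was taken of the probe's own value and the lowest value among probes well above background. Such a fold is not a lower limit, since another background correction can give a smaller one. Single probes of DIP2 and gkt were also tested with an exact two-sided permutation test, whose smallest p with 4 against 4 is 0.0286. The 30 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists, after the 150 values missing through outlier flags (147 genes) were replaced by the mean of the gene's other arrays in the group. With the intensity trend, camera took the trend without robust variance. Shares of changed genes per chromosome were compared with two-sided Fisher's exact tests, adjusted over 6 arms. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

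The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names DIP2 and gkt with every probe, then the 12 largest rises and the 12 largest falls among genes with a symbol that passed the threshold and whose groups did not overlap. From each list it names every member past the threshold, at most 4, or the 2 members with the smallest p as values where none passed. Genes passed over for want of a symbol numbered 9 among the rises and 13 among the falls.

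The test was tried on simulated data for this comparison, built from the means and residual spreads of the 12301 genes tested, with 200 genes changed in each of 20 draws. It recovered 46.6% of genes changed 1.5-fold, 77.3% of those changed 2-fold and 95.3% of those changed 4-fold, and 4.92% of its calls were false. With noise independent between genes, camera found each of 25 lists shifted by 0.5 on the log2 scale and called 0 of the lists without a shift. The noise of the gene test was independent between genes as well. Shifts as small as the list medians of the data were not tried. These rates need not hold for such shifts or for correlated genes.

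Alternatives were quantile and median normalization, normexp background correction with an offset of 50, other filters on dim probes, the authors' value table, the mean of a gene's probes, outlier spots kept, an intensity trend with robust variance, array weights, a slide block, a replicate block, a fold threshold and leaving out each array. Fits on each slide alone and with the level of roX1 as a covariate were added after the data were seen, as were reference-matched genes only and leave-one-out for the chromosome shares and all alternatives for the X chromosome, and the comparisons of the second chromosome and among autosomal genes alone.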

Results

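Gene expression was measured in the central brain of Drosophila pupae at 24 h APF, when the neurons of the mushroom body, a centre for olfactory learning, are being remodelled. Brains in which DIP2 was knocked down in neurons were compared with brains carrying the driver and UAS-dicer2 without the hairpin, with 4 biological replicates and 4 arrays per group. The title of the series places the experiment in a search for genes of axonal bifurcation in the mushroom body and names 1 gene, glaikit (gkt). A total of 12301 genes and transcripts could be tested, 8796 of them with a gene symbol.

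The targeted gene was lower in every knockdown sample at all of its probes but the dimmest. DIP2, which encodes a conserved protein with AMP-binding domains, was read by 4 probes on 3L between 250328 and 256422 (dm3). At the brightest, its mean log2 signal was 1.95 ± 0.13 in control and 1.08 ± 0.17 in knockdown samples (SD, n = 4 each), a 1.82-fold lower level (log2 difference -0.87, SE 0.11, adjusted p = 0.0074). The other probes gave differences of -0.82, -1.30 and -0.52. In an exact two-sided permutation test, p was 0.0286, the smallest that 4 against 4 samples can give, for all DIP2 probes but the dimmest, at which 1 knockdown and 1 control value crossed (p = 0.0571). In the RNA of the dissected tissue the transcript was reduced and not lost. The brightest probe kept 54.9% of its control signal, and the others 56.6%, 40.7% and 69.6%. The hairpin was driven in neurons and the RNA came from all cells of the tissue. What was left of the transcript in neurons can therefore not be told. Whether a probe lies within the hairpin is not given in the sources used here. The difference was -0.94 on slide 1 and -0.79 on slide 2, and with slide as a block the gene passed the threshold as well. The call ended under median normalization (adjusted p = 0.0505), without a filter on dim probes (adjusted p = 0.0624), with the level of roX1 as a covariate (adjusted p = 0.0764) and within single slides (adjusted p = 0.257 and 0.413), and over all alternatives the adjusted p ran from 0.0018 to 0.413.

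At its brightest probe the gene named in the title fell by more than the target did at its own. Another DIP2 probe fell by 1.30, and the falls were not compared by a test. gkt, a member of the phospholipase D superfamily related to tyrosyl-DNA phosphodiesterase, has 2 probes on 2L, at 3162078 to 3162137 and 3162270 to 3162329 (dm3). At the brighter, log2 signal was 1.93 ± 0.14 in control and 0.67 ± 0.10 in knockdown samples (SD, n = 4 each), a 2.40-fold lower level (log2 difference -1.26, SE 0.10, adjusted p = 8.4e-04). The dimmer probe differed by -1.53 (SE 0.14), and both reached the smallest exact permutation p of 0.0286. The difference was -1.25 on slide 1 and -1.27 on slide 2, where 4 arrays alone gave adjusted p of 0.224 and 0.28. CR31953, an uncharacterised locus whose probe lies at 3163088 to 3163147, next to the gkt probes, was 2.42-fold lower (adjusted p = 0.0029).

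**Figure D1:**
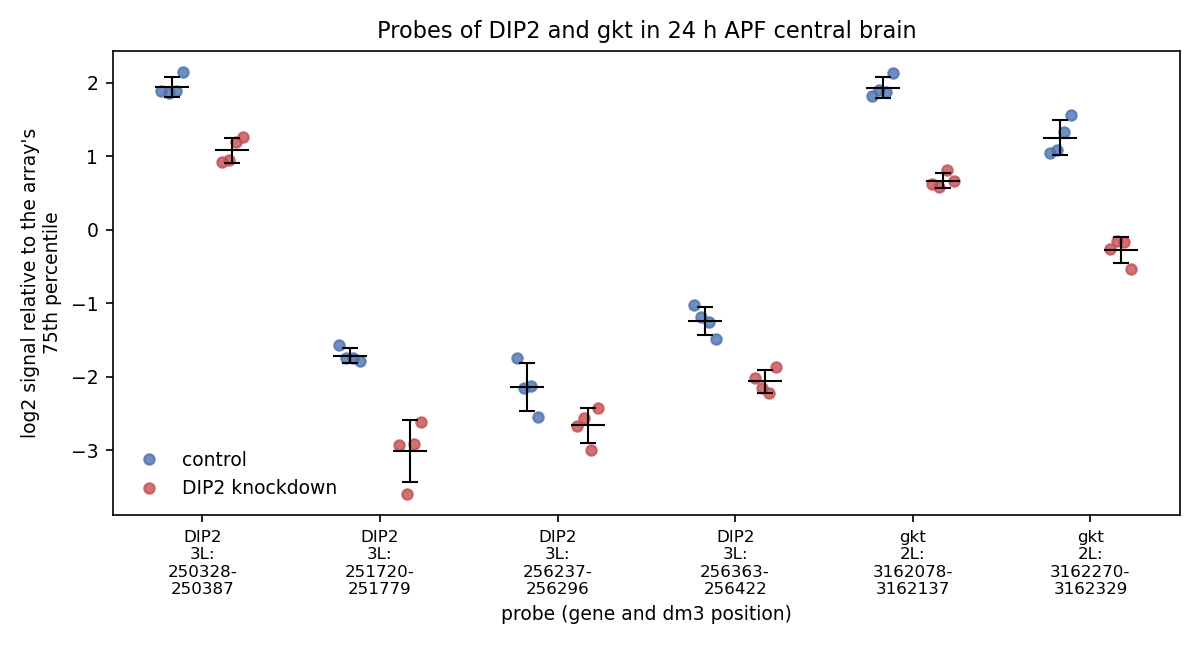
Log2 signal relative to the 75th percentile of each array (vertical axis) for each probe of DIP2 and gkt (horizontal axis, with dm3 position); points are single arrays, horizontal marks are group means and error bars are SDs (n = 4). At both gkt probes and at all DIP2 probes but that at 256237 to 256296, every knockdown value lies below every control value.

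Across the arrays 193 genes and transcripts changed, 94 higher and 99 lower in the knockdown. Of these, 122 carried a gene symbol (60 higher, 62 lower). The median change was 1.77-fold, 35 rose and 31 fell by at least 2-fold, and 47 changed by less than 1.5-fold. In all 193 the 4 knockdown values lay on one side of the 4 control values, as they did in 868 genes, 7.06% of those tested, where chance alone gives 2.86%. Over probes, 232 of 17599 changed (114 higher, 118 lower). With slide as a block 203 genes changed, 172 of them among the 193. On the 4 arrays of slide 1 or of slide 2 limma called 0, with 1518 and 799 genes at an unadjusted p under 0.05, and as gkt did not pass there either, these counts do not speak against the result over all arrays. The count was 101 with normexp correction, 60 without a filter on dim probes, 96 with a replicate block (76 of them among the 193) and 29 with the level of roX1 as a covariate. It was 113, 106 and 114 without control 1, 2 or 3 and 107, 128, 101 and 99 without DIP2 knockdown 1, 2, 3 or 4.

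The largest measured rises were in genes with little or no signal in control brains, so their size depends on the handling of background. The normexp correction added an offset of 50 to each intensity, which by itself shrinks the log2 differences of dim probes. This applies to the normexp values of all dim genes given here and below. Against the floor, Ugt301D1, a UDP-glycosyltransferase, was 7.44-fold higher (adjusted p = 8.4e-04) and mRpL48, a protein of the mitochondrial ribosome, 8.52-fold (adjusted p = 0.0015). By the same measure defl was 2.92-fold higher (adjusted p = 8.4e-04). The probes of these genes were well above background in no control sample and in all 4 knockdown samples. For mRpL48 the fold against the floor equals the measured one. Without DIP2 knockdown 3 another probe stood for Ugt301D1 and its difference was 0.80 (adjusted p = 0.744). Without a filter on dim probes it was 0.58 (adjusted p = 0.696). With normexp correction Ugt301D1 differed by 1.13 on the log2 scale (adjusted p = 0.0185), and the calls of mRpL48 (1.25, adjusted p = 0.0637) and defl (0.49, adjusted p = 0.867) ended. CG10936 rose 6.01-fold (adjusted p = 0.0022) and Dnaaf3, an assembly factor of axonemal dynein, 4.47-fold (adjusted p = 0.003), each with 3 of 4 control samples above background. With normexp correction they differed by 1.53 and 1.14 on the log2 scale and kept the call. CecA1, an antimicrobial peptide of the cecropin family, rose 2.70-fold (adjusted p = 0.017), Cpr57A, a cuticle protein, 2.48-fold, tut 2.34-fold and CG4998 2.26-fold. The call of CecA1 ended without DIP2 knockdown 1, 2 or 4 (adjusted p = 0.0594, 0.0678 and 0.0675), and that of CG4998 without control 1, 2 or 3 or DIP2 knockdown 1 or 2 (adjusted p up to 0.0591). With normexp correction both ended (0.73 and 0.72, adjusted p = 0.273 and 0.197). CG42749 rose 2.89-fold (adjusted p = 0.0442), a call kept without DIP2 knockdown 2 and lost without any of the other arrays (adjusted p up to 0.149).

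Probes disagreed within some of these genes. Syt7, a synaptotagmin of membrane fusion, rose 2.69-fold at its brightest probe (adjusted p = 0.008) and by 1.30 on the log2 scale at a further probe, while its dimmest differed by -0.23. Pfk, phosphofructokinase of glycolysis, rose 2.47-fold at its brightest probe (adjusted p = 8.4e-04), while its other probes differed by -0.05 and -0.11. Of the 12 named genes with more than 1 tested probe, 8 had all other probes changed the same way by at least 0.5 of the log2 size. With the mean of a gene's probes in place of the brightest, the differences of Pfk and Syt7 were 0.38 and 0.83 and their calls ended. The probes of CG42749 did not disagree (1.53 and 1.55), and with their mean the difference was 1.54 although the call ended (adjusted p = 0.108).

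**Figure D2:**
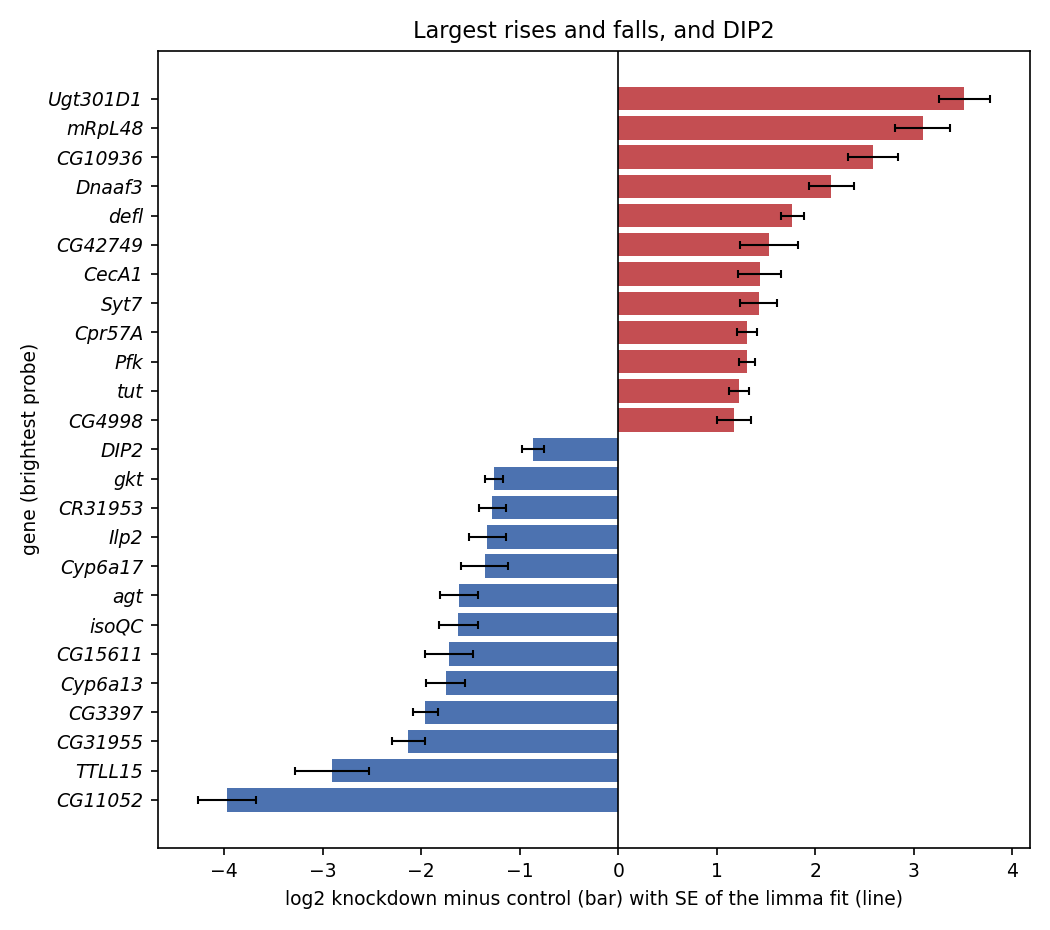
Log2 difference, knockdown minus control (horizontal axis), of the 12 largest rises, the 12 largest falls and DIP2 (vertical axis); bars are estimates for the brightest probe and lines their SE (limma, n = 4 per group). The largest measured differences are those of Ugt301D1 (3.51) and CG11052 (-3.97), and in Ugt301D1, mRpL48, defl and TTLL15 the dimmer group was not well above background.

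The falls included a neuropeptide and several enzymes. Ilp2, an insulin-like peptide of the neurosecretory cells in the brain, was 2.51-fold lower (log2 difference -1.33, SE 0.18, adjusted p = 0.011). The cytochrome P450 genes Cyp6a13 and Cyp6a17 were 3.37-fold and 2.56-fold lower (adjusted p = 0.0041 and 0.032), agt, an alkyltransferase that repairs methylated guanine in DNA, 3.06-fold (adjusted p = 0.0059), and CG15611 3.29-fold (adjusted p = 0.012). CG11052, with the largest measured fall, differed by 15.7-fold (adjusted p = 8.4e-04) and was well above background in 4 control samples and 1 knockdown sample. TTLL15, of the tubulin tyrosine ligase family, was 7.51-fold lower (adjusted p = 0.0074), both as measured and against the floor. CG31955 was 4.38-fold and CG3397 3.88-fold lower. isoQC, a glutaminyl cyclase that modifies the ends of peptides, was 3.08-fold lower at its brightest probe (adjusted p = 0.0059) and differed by -0.07 at its dimmer one. agt was well above background in 2 and Cyp6a17 in 3 of the 4 knockdown samples. With normexp correction the log2 differences were smaller and the calls ended for CG11052 (-1.56, adjusted p = 0.0769), TTLL15 (-0.67, adjusted p = 0.845), CG31955 (-1.03, adjusted p = 0.0541), CG15611 (-0.92, adjusted p = 0.269), agt (-0.53, adjusted p = 0.867) and Cyp6a17 (-0.54, adjusted p = 0.867). CG3397 kept it at -1.35. The call of Ilp2 ended without a filter on dim probes (adjusted p = 0.0656) and with a replicate block (adjusted p = 0.0564). With the level of roX1 as a covariate the calls of gkt, Ugt301D1, mRpL48, defl, Cpr57A, Pfk, tut, CG11052, CG31955 and CG3397 held and those of the other genes shown in the figure ended. The differences changed little in size: over all 193 called genes the log2 difference with roX1 was a median of 0.973 of that without (quartiles 0.896 and 1.05), and 193 kept their direction. The call of Cyp6a17 held without DIP2 knockdown 1 or 3 and ended without any of the other arrays (adjusted p up to 0.103).

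By gene list, 7 of the 30 lists held a member that changed. Among 46 tested genes of detoxification, GstE1, a glutathione transferase, rose 2.07-fold (adjusted p = 0.011), while Cyp6a13, Cyp6a17 and GstE8 fell, the last with a difference of -0.58 on the log2 scale (adjusted p = 0.037). The counts adjusted over the list alone were again 1 higher and 3 lower. Among 39 genes of DNA repair and cell death, the photolyase gene phr rose 2.12-fold (adjusted p = 0.0046) and PolZ1, the catalytic subunit of a translesion polymerase, 1.39-fold (adjusted p = 0.0465, log2 difference 0.47, and 0.21 at its dimmer probe), and spn-B, a meiotic recombination gene, fell 1.55-fold (adjusted p = 0.015), with the same counts adjusted over the list alone. The probes of phr and PolZ1 lie near each other on 2R, at 3714762 and 3688478 (dm3), so their calls need not be independent. Camera gave adjusted p = 0.705 for detoxification (median log2 difference 0.06) and 0.709 for DNA repair (0.02). Ilp2 was the 1 changed gene of 33 neuropeptides (median -0.06, adjusted p = 0.506) and CecA1 that of 31 immune genes (median 0.03, adjusted p = 0.709). In the list of driver and RNA interference genes, 1 of 7 rose: w, the eye colour gene used as a marker in many transgenes, was 1.51-fold higher (adjusted p = 0.0445), and elav, Dcr-2 and AGO2 differed by 0.11, -0.01 and 0.06 at their brightest probes (median of the list 0.10, adjusted p = 0.282). w was also the changed gene among 13 of the photoreceptor list (median 0.05, adjusted p = 0.709). The calls of GstE8, PolZ1 and w ended with slide as a block (adjusted p = 0.051, 0.0622 and 0.0571) and in 7 of the 8 fits that left out an array, being kept without control 4 for GstE8 and PolZ1 and without control 1 for w. That of spn-B ended without DIP2 knockdown 1 or 3 or control 3 (adjusted p up to 0.0652). With normexp correction the calls of w, GstE8, PolZ1 and spn-B ended, spn-B at -0.15 (adjusted p = 0.999). That of spn-B ended also with quantile and median normalization, the authors' values and an intensity trend (adjusted p = 0.218, 0.137, 0.377 and 0.162).

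In the fixed lists of axon growth, branching and synapses, which hold neither gkt nor Syt7, no member passed the threshold over all genes or adjusted over its list alone. This held for 47 genes of axon guidance (median log2 difference 0.04, camera adjusted p = 0.33), where the smallest p were those of 18w (0.25) and Sema2b (0.30), for 37 of the growth cone cytoskeleton (median 0.05, adjusted p = 0.195), with shot at 0.26 and ena at 0.46, and for 21 of axon pruning (median 0.05, adjusted p = 0.429), with put at -0.33 and Mical at 0.16. It held likewise for 34 genes of synapses and transmission (median 0.03, adjusted p = 0.628), where Rdl differed by 0.33 and Nlg1 by -0.45, for 24 of the ecdysone response (median 0.08, adjusted p = 0.166), where Ldh differed by 0.55 and ImpE2 by 0.64, and for 21 glial genes (median 0.01, adjusted p = 0.901), where alrm differed by -0.34 and moody by 0.30. As wholes and with the preset correlation, the lists of axon guidance, growth cone cytoskeleton and synapses passed the threshold, upwards, with the level of roX1 as a covariate (adjusted p = 0.0233, 0.0073 and 0.0233), with array weights (adjusted p = 0.0324, 0.0149 and 0.0388) and without a filter on dim probes (adjusted p = 0.0021, 9.2e-04 and 0.036). Axon guidance and the cytoskeleton passed without control 4 (adjusted p = 0.0324 and 0.0061), the cytoskeleton without DIP2 knockdown 4 (adjusted p = 0.047), axon pruning without a filter (adjusted p = 0.0207), and the ecdysone response without a filter and on slide 2 (adjusted p = 0.0015 and 0.0141). With an estimated correlation none of these lists passed in any of these settings, and axon guidance, the cytoskeleton and synapses had adjusted p of 0.866 each with roX1, 0.663, 0.673 and 0.706 with array weights and 0.325, 0.424 and 0.557 without a filter. Without the filter the medians of axon guidance, the cytoskeleton, axon pruning and the ecdysone response did not move. That of all genes tested went from -0.01 to -0.12. Camera compares a list with the other genes, so the passes without a filter do not show a rise of these lists.

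Of the lists, 4 passed the threshold as a whole with the preset correlation. DIP2 and gkt together (median -1.06) gave adjusted p = 1e-05, but gkt is in the list because the series title names it, so this is not independent evidence (adjusted p = 0.253 with an estimated correlation). The 29 genes of neuroblasts and cell division had a median of 0.10 (adjusted p = 0.0037, and 0.83 with an estimated correlation), with aurB, a mitotic kinase, at 0.42 and E2f1 at 0.30. The 28 genes of mushroom body neurons had a median of 0.06 (adjusted p = 0.039, and 0.83 with an estimated correlation), with Imp, an RNA-binding protein of early-born neurons, at 0.26 and the adenylate cyclase rut at 0.31. The 8 tracheal genes had a median of 0.21 (adjusted p = 0.039, and 0.818 with an estimated correlation), with dpy, a matrix protein, at 0.73, past the threshold adjusted over the list alone, and knk at 0.37. No member of the lists of cell division, mushroom body neurons and trachea passed the threshold over all genes. Over all alternatives the medians of these lists ran from 0.03 to 0.18, 0.03 to 0.14 and 0.09 to 0.35. The highest values of cell division and mushroom body neurons were those with median normalization, which moved differences upwards by a median of 0.08 over genes. With slide as a block their adjusted p were 0.0027, 0.0469 and 0.0338. On slide 1 and slide 2 alone the medians were 0.08 and 0.09 for cell division (adjusted p = 0.0275 and 0.0385), 0.11 and 0.09 for mushroom body neurons (adjusted p = 0.137 and 0.0756) and 0.22 and 0.35 for trachea (adjusted p = 0.139 and 0.0267). The mushroom body call ended without control 1, 2 or 3 or DIP2 knockdown 3 (adjusted p up to 0.377). It ended also with quantile and median normalization, the authors' values and the mean of probes (adjusted p = 0.0599, 0.129, 0.142 and 0.305). The tracheal call ended without control 1 or 3 or DIP2 knockdown 1, 3 or 4 (adjusted p up to 0.193), and with quantile normalization or outlier spots kept (adjusted p = 0.0529 and 0.144). That of cell division ended with array weights (adjusted p = 0.0541). With the level of roX1 as a covariate those of cell division and trachea ended (adjusted p = 0.202 and 0.215), and mushroom body neurons passed (adjusted p = 0.0069).

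**Figure D3:**
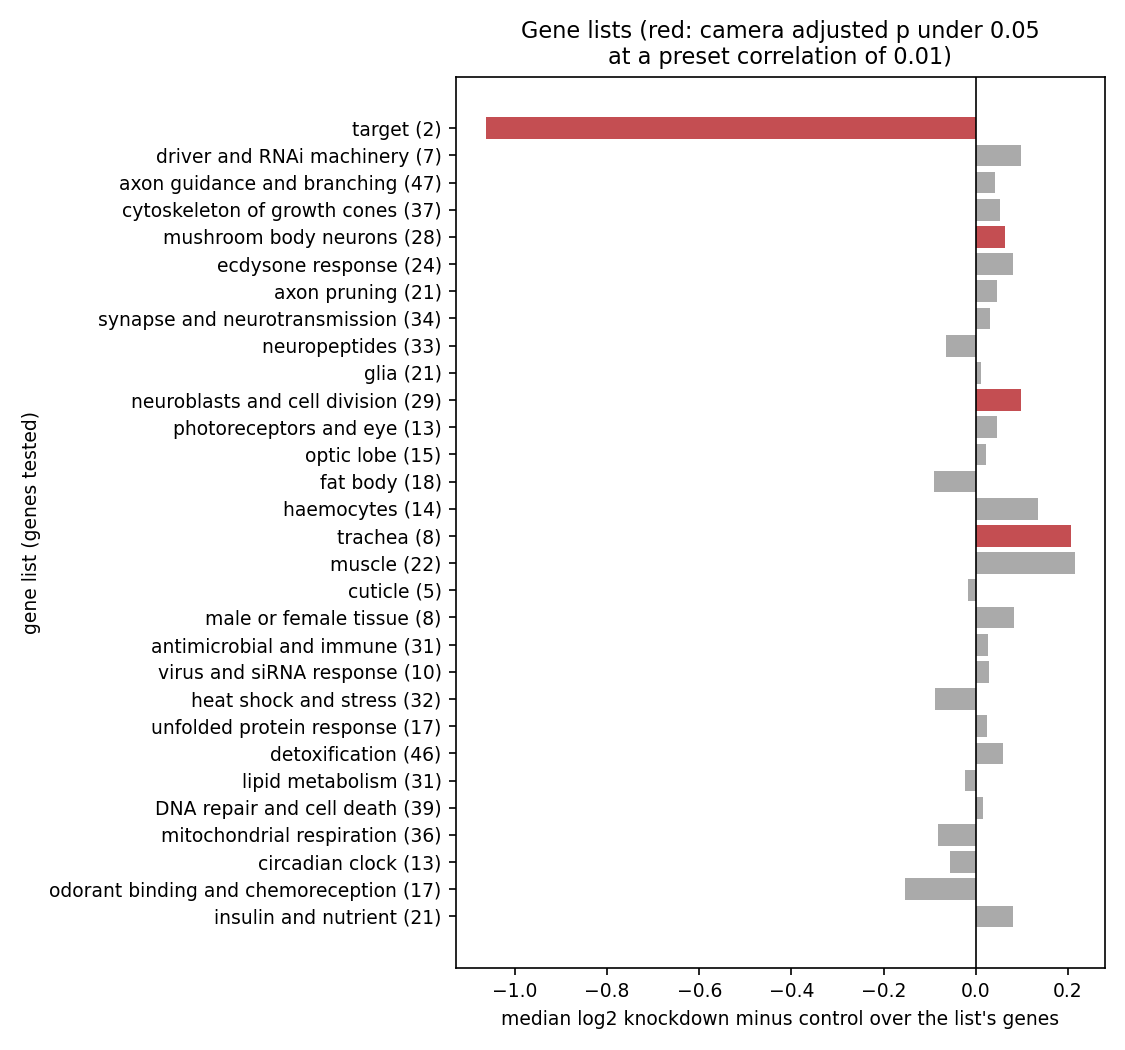
Median log2 difference, knockdown minus control (horizontal axis), over the tested genes of each list (vertical axis, number of genes in parentheses); red bars passed the threshold with camera at the preset correlation. Besides the target list at -1.06, all medians lie between -0.15 and 0.22.

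The remaining lists did not pass. Muscle did under 6 of 23 alternatives (adjusted p = 0.0104 without control 1, 0.0019 without DIP2 knockdown 3, and 0.0073 with the level of roX1) and respiration under 3 (0.0104 without control 1). Haemocytes (0.0447 without control 1), insulin and nutrient genes and neuropeptides passed under 1 each. With an estimated correlation none of them passed in any setting (0.78, 0.913 and 0.954 for the muscle values given). Among tissues that could adhere to the brain, medians were 0.02 for 15 optic lobe genes (adjusted p = 0.709, with ct at 0.19 and Optix at -0.16), -0.09 for 18 fat body genes (adjusted p = 0.749, Fbp2 at -0.62 and FASN1 at -0.34), 0.14 for 14 haemocyte genes (adjusted p = 0.234, LanB1 at 0.28 and LanA at 0.17), 0.22 for 22 muscle genes (adjusted p = 0.211, Act57B at 0.40 and Mef2 at 0.21, and a median of -0.20 without DIP2 knockdown 1, 0.59 without DIP2 knockdown 3, 0.45 without control 1, 0.07 without control 3 and 0.06 without control 4) and -0.02 for 5 cuticle genes (adjusted p = 0.749, Edg91 at 0.34 and Cpr97Eb at 0.11). Leaving out 1 array moved the median of fat body genes to between -0.29 (without DIP2 knockdown 1) and 0.05 (without DIP2 knockdown 2) and that of cuticle genes to between -0.23 (without DIP2 knockdown 1) and 0.32 (without DIP2 knockdown 3). Without control 4 the medians of the immune, sex and photoreceptor lists were -0.21, -0.23 and -0.14. Among responses and metabolism, medians were 0.03 for 10 genes of the response to viruses (adjusted p = 0.429, ref(2)P at 0.21 and Socs36E at 0.18), -0.09 for 32 of heat shock and stress (adjusted p = 0.41, GstD7 at -0.74 and Hsp70Bb at -0.44), 0.02 for 17 of the unfolded protein response (adjusted p = 0.902, Xbp1 at -0.28 and Thor at -0.51) and -0.02 for 31 of lipid metabolism (adjusted p = 0.705, Fatp1 at -0.32 and Dgk at -0.30). They were -0.08 for 36 genes of respiration (adjusted p = 0.159, ND5 at 0.85 and SdhC at -0.25), -0.06 for 13 clock genes (adjusted p = 0.945, Pdf at -0.33 and sgg at 0.26), -0.15 for 17 chemosensory genes (adjusted p = 0.506, Obp83a at 0.69 and Obp56a at 1.02) and 0.08 for 21 insulin and nutrient genes (adjusted p = 0.331, Thor at -0.51 and Akt at 0.20). Adjusted over its list alone, 1 gene each was lower in heat shock and stress and in lipid metabolism. Adjusted over the list alone the immune list and the photoreceptor list each held 1 gene higher and 1 lower. Median and mean differed in sign in 7 lists, those of glia, photoreceptors, cuticle, sex, immunity, the unfolded protein response and detoxification.

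The samples differed in RNA that marks male cells. roX1 and roX2, the noncoding RNAs of male dosage compensation, were well above background on 8 and 7 of the 8 arrays, all labelled female. Log2 signal of roX1 ran from 0.13 to 1.59 in control samples and stood at 0.98, -1.30, 0.31 and -3.19 in DIP2 knockdown 1 to 4. The group difference was -1.94 (limma adjusted p = 0.517), and an exact two-sided permutation test gave p = 0.0857 for roX1 and 0.2 for roX2. The 8 tested genes of the sex list had a median of 0.08 (camera adjusted p = 0.628), with msl-2, a protein of the same complex, at 0.21.

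The summary of the series writes the hairpin in the place of the third chromosome, while the sample labels set it after a single semicolon, the place of the second. The third was chosen beforehand, from the summary, and the share of changed genes was compared between it and the others, and for each arm. On the third chromosome 77 of 5145 genes changed, against 98 of 6655 elsewhere (odds ratio 1.02, 95% interval 0.743 to 1.39, Fisher's exact p = 0.939). On the second, which was not in the plan, 88 of 4287 changed (2.05%) against 87 of 7513 elsewhere (1.16%, odds ratio 1.79, 95% interval 1.31 to 2.44, Fisher's exact p = 1.8e-04). Among autosomal genes alone, compared after these values were seen, the odds ratio was 1.37 for the second (95% interval 0.996 to 1.88, Fisher's exact p = 0.0506) and 0.728 for the third (95% interval 0.529 to 0.9995, Fisher's exact p = 0.0432). At an unadjusted p under 0.01 the odds ratio of the third was 0.776 (Fisher's exact p = 0.0083), below 1. The X chromosome had few changed genes, 6 of 2153 (0.279%) against 169 of 9647 (1.75%) elsewhere (odds ratio 0.157, 95% interval 0.0567 to 0.349, adjusted p = 2.6e-08). The 6 were b6, CG3857, CG42749, Rtel1, w and a transcript without a gene symbol. Their probes all lay between 1584153 and 5645759 on the X (dm3). Arm 2L had 46 of 2020 (2.28%, odds ratio 1.74, adjusted p = 0.0067), and 2R, 3L, 3R and 4 had shares of 1.33% to 1.86% (adjusted p from 0.242 to 0.564). Genes are not independent replicates, and neighbouring transcripts can overlap, so these p describe the spread over genes of 8 arrays.

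**Figure D4:**
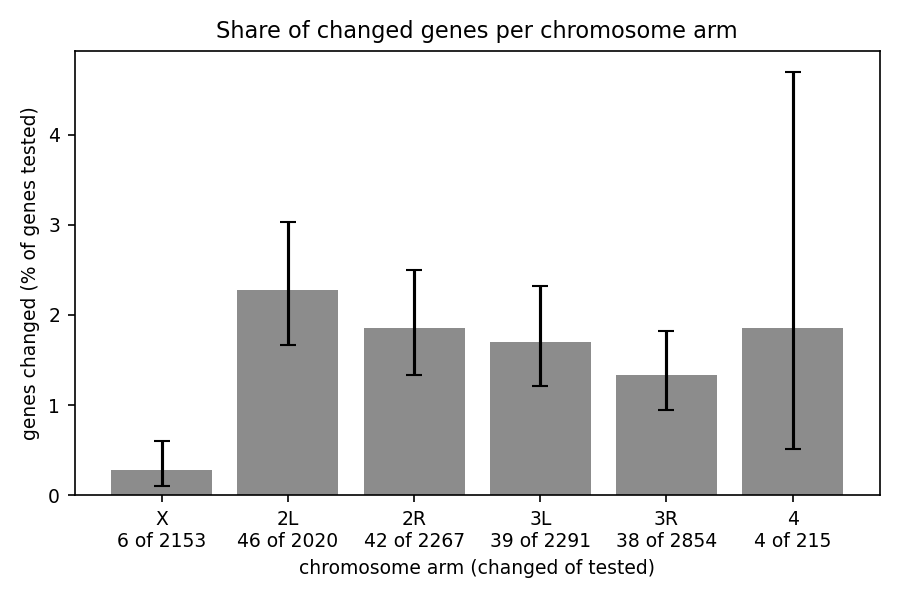
Share of tested genes that changed (vertical axis, percent) on each chromosome arm (horizontal axis, with counts); error bars are exact Clopper-Pearson 95% intervals over genes. The X chromosome, at 0.279%, lies below all other arms, which range from 1.33% to 2.28%.

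Around gkt the share was higher than on the rest of its arm. Within 500 kb of its probe, 8 of 116 other genes and transcripts changed (6.90%), against 37 of 1903 on the rest of 2L (1.94%, odds ratio 3.73, 95% interval 1.46 to 8.40, Fisher's exact p = 0.0033). CR31953, RpS21 and NTPase were lower there, by 2.42, 1.60 and 1.43-fold, and CG17264, CG15412 and Spindly higher, by 2.01, 1.84 and 1.72-fold. These neighbours besides CR31953 were named for their place, after their values were seen. Among the 8, CG17264 and a transcript without a gene symbol have probes that start at the same place (3021442) and rose alike (1.00 and 1.07). They are therefore not separate findings, although the counts above treat them so. With named genes alone and without CR31953 the counts were 5 of 91 and 26 of 1459 (odds ratio 3.20, 95% interval 0.937 to 8.76, Fisher's exact p = 0.0315).

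**Figure D5:**
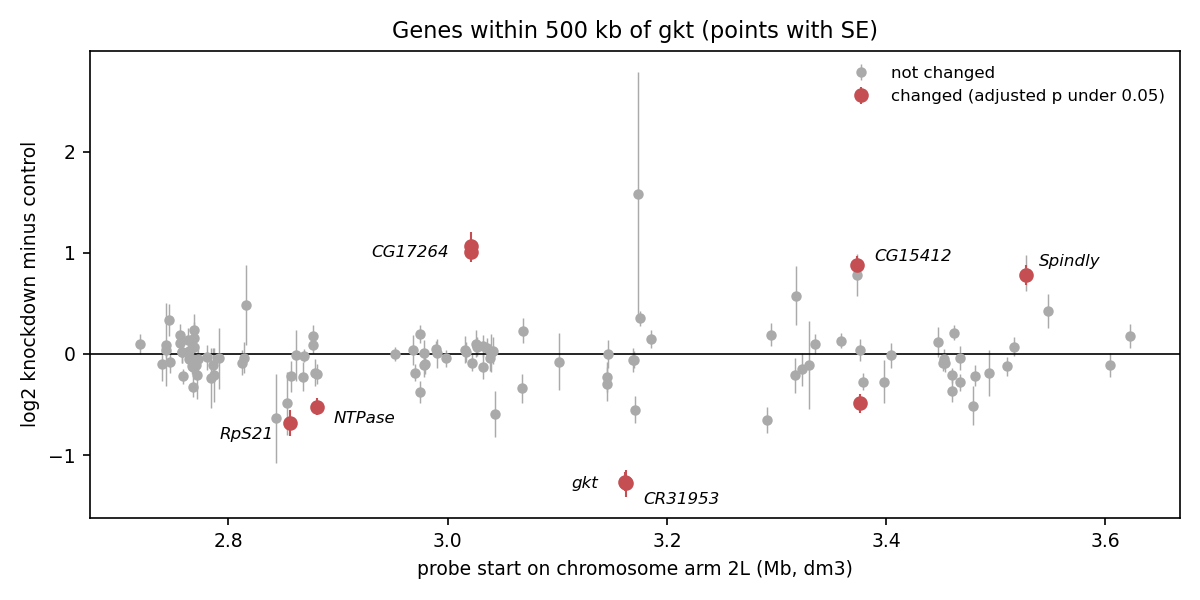
Log2 difference, knockdown minus control (vertical axis), of each tested gene or transcript within 500 kb of gkt by probe start on 2L (horizontal axis, Mb, dm3); points are limma estimates with SE (n = 4 per group), red where adjusted p passed the threshold. gkt and CR31953 lie side by side at -1.26 and -1.28, and CG17264, CG15412 and Spindly lie above 0.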

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

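Within each group of 4, the highest and lowest samples were compared with the nearest other sample, as the gap divided by the group's range, for each named gene and for the mean of each list. Of 218 such group values 11 had a ratio above Dixon's 95% limit for 4 samples, and chance alone gives about 1 in 20.

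Control 4 stood apart in 5 of these. It was the highest control for DIP2 (2.15 against 1.89 in the nearest control, ratio 0.932) and hence for the mean of DIP2 and gkt (ratio 0.884), and the lowest for isoQC (2.54 against 3.06, ratio 0.857), Mef2 (1.13 against 1.58, ratio 0.857) and the mean of the ecdysone response list (-0.02 against 0.20, ratio 0.864). This array had the lowest share of spots well above background, 52.3%. In other control samples, Ilp2 was lowest in control 2 (0.757 against 1.102, ratio 0.908), and the mean of the list of responses to viruses was lowest in control 3 (1.32 against 1.36, ratio 0.858).

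Among knockdown samples, DIP2 knockdown 2 was lowest for CG31955 (-4.55 against -3.95, ratio 0.902) and GstE1 (-1.11 against -0.74, ratio 0.913) and highest for Mical (2.10 against 1.92, ratio 0.936). DIP2 knockdown 3 was lowest for CG3397 (-2.88 against -2.46, ratio 0.887). For CG31955, CG3397, isoQC, Ilp2, DIP2 and GstE1 the call held when the sample in question was left out. These are given as values, and no explanation of them was tested.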

How the results depend on the processing

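The fits on single slides, the fit with roX1, the comparison among autosomal genes and the alternatives for the X chromosome were chosen after the data were seen. The count of 193 genes (232 probes) moved to 101 (120) with normexp, to 60 (81) without a filter on dim probes, where 23616 genes were tested, and to 29 (41) with roX1 as a covariate. On slide 1 alone and on slide 2 alone limma called 0 genes and 0 probes, with 2 arrays per group. Leaving out 1 array gave 99 to 183 genes and 113 to 199 probes. Besides the replicate block, the other alternatives gave between 146 (with a fold threshold) and 289 genes (array weights). Normexp added an offset of 50 to each intensity, while the median processed intensity ran from 49.1 (control 3) to 96.5 (control 1). Such an offset by itself shrinks the log2 differences of dim probes. How much of the lower count it accounts for was not tested. Median normalization called 155 genes, 67.7% of them higher against 48.7% of the 193, with the median of all genes shifted by 0.08.

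DIP2 stayed lower throughout and lost the threshold under median normalization (-0.78), without a filter (-0.87), with roX1 (-0.94, adjusted p = 0.0764) and on slide 1 (-0.94) and slide 2 (-0.79), and gkt on slide 1 (-1.25) and slide 2 (-1.27) only. Median normalization moved the differences upwards by a median of 0.08 over genes, and the smaller fall of DIP2 there goes with this shift. Whether the shift alone ended the call was not tested. Without a filter more genes were tested, and on single slides fewer arrays. Leaving out 1 array kept both calls. Of 657 values of the other 29 named genes, 486 stayed past the threshold, 171 did not and 0 changed sign. In fits that left out arrays, the sign at the same probe could not change, since the groups of these genes did not overlap. The 4 lists past the threshold became 2 with quantile normalization, 11 without a filter, 0 with an estimated correlation and 1 with fry for a shared direction, and 2 to 6 without 1 array. Without a filter the median of all genes went from -0.01 to -0.12, and camera compares a list with the other genes. Otherwise the cause was not tested. For change in either direction fry gave 5 lists, photoreceptors (adjusted p = 1.1e-05), detoxification and DNA repair (7.4e-04 each), lipid metabolism (0.001) and the driver list (0.0081). Unlike camera, fry does not compare a list with the other genes, so a few changed members can be enough. All of these lists but lipid metabolism hold called genes, and w is in both the photoreceptor and the driver list. The odds ratio of the third chromosome went from 1.02 to 0.776 at an unadjusted p under 0.01, and the cause was not tested, and to 0.728 among autosomal genes, where the X with few changed genes is left out. Its other values were not past the threshold. The odds ratio of the X stayed between 0.0452 and 0.366.

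With a replicate block 96 genes (99 probes) changed, 76 of them shared. Deviations of samples with the same number correlated at 0.33, 0.21, 0.20 and -0.27 over genes, and control samples 1 and 2 but not 3 and 4 correlated best with their own number, so the numbers were not taken to pair samples. A block by scan date equals that by slide, and position on the slide could not be fitted beside group, so neither was run. A probe well above background on no array of a group gives a fold against a floor only, which limits 6 of the called genes.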

Other observations

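The tests of a variant under a gkt probe and of roX1 and roX2, the count of named genes around gkt, the windows and the fits on single slides and with roX1 were chosen after the results were seen, and the test of roX1 between the groups replaced one on its range once the values were known. The explanations below were found and tested on the same data and are hypotheses.

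Some changed genes lay close together on the autosomes, and the 6 on the X lay between 1584153 and 5645759 (dm3). In overlapping windows of 1 Mb with at least 20 tested genes, the highest share was on 3R between 3 and 4 Mb (dm3), where 9 of 83 changed, among them CG11052, the gene with the largest measured fall. The next was on 2L between 3 and 4 Mb, with 8 of 94, among them gkt and CG31955, and then 2R between 15 and 16 Mb, with 6 of 74. Of 238 windows, 7 had a share at least as high as that around gkt (6.90%), but 2 of these hold gkt itself, which the share around it leaves out. These windows were described and not tested. The retinal opsin gene ninaE had a log2 signal of -0.46 in DIP2 knockdown 1 and between -4.68 and -2.91 in the other samples. The fat body protein gene Lsp2 was well above background on all 8 arrays.

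The number of changed genes was set against other splits of the 8 arrays into 4 and 4. Of 35 splits, 2 called as many genes as the real one, which called 193, so by this count chance is not excluded. The other is the split by slide, with 553 genes, several times the real count, which points to a structure of the samples, and the remaining splits called 3 or fewer. The slides held both groups equally, and with slide as a block the comparison of the groups called 203 genes, 172 of them among the 193. Within slide 1 and within slide 2, with 2 arrays per group, limma called 0 each (1518 and 799 at an unadjusted p under 0.05), and gkt at -1.25 and -1.27 did not pass either, so these counts decide nothing.

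Changed genes were rare on the X chromosome (6 of 2153, with an odds ratio of 0.0452 without DIP2 knockdown 1 to 0.178 without control 3, against 0.157 with all arrays). Lower signal of X genes does not account for this, since within quintiles of mean signal the common odds ratio was 0.153 (95% interval 0.0674 to 0.346). The series summary writes the driver and UAS-dicer2 in the place of the X in both genotypes, so a candidate explanation is that the X chromosomes were alike and the autosomes, besides the hairpin, were not. The 6 changed X genes all lay between 1584153 and 5645759 (dm3). Among them w is a marker in many transgenes, so its RNA need not come from its place on the X. Going by the others, the X chromosomes may not have been alike in that stretch. Neither was tested. An unadjusted p under 0.05 was also rarer on the X among genes not called changed (5.03% against 8.66%, odds ratio 0.559, 95% interval 0.45 to 0.688), but a response to DIP2 loss that spares X genes predicts this as well, so it does not favour either. Sequence variants under single probes stay open, since in 24 of 45 changed autosomal genes with more than 1 probe (53.3%, 95% interval 37.9 to 68.3) all other probes changed alike, and so does such a response, which was not tested apart.

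The fall of gkt was not from a single probe, as the smaller fall of its probes was 0.824 of the larger on the log2 scale, nor from 1 slide, as the smaller of the falls on the slides was -1.25. The share of changed genes within 500 kb was above that on the rest of 2L (odds ratio 3.73), as a difference of genotype in that region would predict, although with named genes alone and without CR31953 the interval reached 0.937. A linked difference between the fly stocks may therefore contribute to the level of gkt and of CR31953 beside it. An effect of the DIP2 knockdown on gkt stays open as well and was not tested apart from this, since the arrays hold no second hairpin.

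roX1 and roX2 rose and fell together over the 8 arrays (Pearson r = 0.99, exact permutation p = 8.2e-04; Spearman rho = 0.786, p = 0.0279; r = 0.896 without the 2 arrays farthest from the median of roX1; 1 relation computed). The relation was not computed within a group or a slide, each of which holds 4 arrays. Male tissue in some of the samples labelled female could give such a pattern, with less of it in DIP2 knockdown 2 and 4, and both RNAs come from the X. A response to the knockdown cannot be told apart from it. The exact permutation test of roX1 between the groups gave p = 0.0857 with 4 samples each. By replicate number, roX1 was lower in the knockdown sample for all 4 (-0.61, -1.43, -0.996 and -4.70), and an exact sign-flip test gave p = 0.125, the smallest it can give. The numbers were not taken to pair samples, so the sign-flip test rests on a pairing that is not established. With roX1 as a covariate 29 genes stayed past the threshold, gkt among them, while the differences of the 193 kept their direction and a median of 0.973 of their size, so the lost calls do not show that roX1 accounts for them.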
